A study of Mus musculus with 2 samples.

How the data were processed

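Liver RNA of BALB/c mice at day 11 after birth was measured in 1 wild-type and 1 SRSF2 knockout library, grouped by the genotype in the labels. Per the labels' protocols, livers were frozen in liquid nitrogen, RNA was extracted with Trizol and libraries followed standard Illumina procedures. The submitters' processing notes name the aligner Bowtie 0.12.2 and the mouse genome build mm9. The counting program, the annotation release, the treatment of reads that map to several places, the use of strand and any pooling of animals are not given in the sources used here. Reads shared by near-identical genes, or by a gene and an antisense partner, may therefore be divided or lost in an unknown way.

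The deposited tables give, per the file headers, a read count and an FPKM for each RefSeq accession, both made by the authors. The deposited counts are whole numbers that sum to 22407743 reads in the wild-type and 22111605 in the knockout table. The deposited FPKM values are the authors' normalization by transcript length and library size. The FPKM worth of 1 read differed between the tables by a factor of 1.012, which held within 1% for 98.6% of the 12924 accessions with at least 20 reads in each library. Each table has 26462 lines for 26449 accessions, because 13 accessions stand on 2 lines, which were summed. Of the accessions, 17460 had reads in the wild-type and 19218 in the knockout library. A small positive FPKM stood beside 0 reads on 255 lines of the wild-type table (at most 0.349) and 312 of the knockout table (at most 0.389), and these values were kept as deposited.

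Gene symbols came from a RefSeq gene table of assembly GRCm38.p6 and GENCODE accession tables, used for names and not for coordinates, since the build differs. Names were found for 23419 accessions, 23223 by transcript accession, 75 by protein accession and 121 through GENCODE. The other 3030 accessions kept their accession as a name and took 1.99% of the wild-type and 1.98% of the knockout reads. For 9 genes, 2 accessions were summed, which left 26440 genes. A few list members, such as Igf1, Csf1r and Srsf11, were not matched and were not analysed here.

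The size of a difference was log2((knockout FPKM + 1) / (wild-type FPKM + 1)) for genes with an FPKM of at least 1 in either library, 12477 genes. The pseudocount of 1 understates the change of genes with low values. With 1 library per genotype no p-value or standard error was computed, and genes were described by a fixed size rule of 2-fold. Folds printed in the text are plain FPKM ratios, with exact Clopper-Pearson 95% intervals of the read ratio, scaled by the factor above. They cover counting error only, since reads from amplified libraries are not independent molecules. For genes at 0 reads in the wild-type library the fold is taken against a floor of 3 reads in that library. The lower limit of the exact interval is given beside it.

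The 41 gene lists (31 pathways or gene classes and 10 cell type marker lists), a sex chromosome list, the filter, the size rule, the rule for named genes and most alternatives were fixed before the data were examined. A list was described by its median log2 ratio, the members past 2-fold, and the percentile of the median among 10000 random lists of the same size, drawn from the same 20 bins of mean expression. Lists in the lowest or highest 2.5% are said to stand apart, as a description of these libraries. The median over all genes was not 0, so list medians are also given relative to it. The text names Srsf2 and other SR proteins, and the 12 highest and 12 lowest ratios among genes with at least 10 FPKM in a library and above 0 in both, without predicted or unnamed genes. It also names up to 4 members of each list (the 3 with the largest absolute log2 ratio and the most abundant), the 5 most abundant genes of each library, and up to 3 genes per direction with at least 10 FPKM in a library and 0 in the other. A gene outside this rule is said to have been chosen after its values were seen.

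Alternatives changed 1 choice at a time: a pseudocount of 0.1 or 5, no filter or a filter of 5 FPKM, rescaling to a common sum (TPM), centring on the median of all genes, rescaling without the 20 most abundant genes, a gene represented by its highest accession, and size rules of 1.5-fold and 4-fold. Counts without the listed sex chromosome, pancreatic and skeletal muscle genes, counts by the read ratio interval without a pseudocount, and 12 further gene lists were added after the data had been seen. The computation was tested on simulated libraries of 12477 genes with 100 genes raised and 100 lowered 4-fold. It called 100% of the raised and 77% of the lowered genes at 2-fold, and 29 unchanged genes. The simulated intervals held the true ratio for 95.5% of genes. Of simulated lists with no effect, whose genes varied independently, 3.67% lay outside the random range. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.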

Results

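Liver transcripts of BALB/c mice were sequenced on an Illumina HiSeq2000 at day 11 after birth. There was 1 library from wild-type liver and 1 from liver labelled SRSF2-/- (the knockout library). SRSF2 is a serine/arginine-rich (SR) protein that binds exons and takes part in the splicing of messenger RNA precursors. The comparison asked how the liver transcriptome of young mice differs with this genotype. The wild-type library held 22407743 reads on annotated transcripts and the knockout library 22111605. With 1 library per genotype there was no replicate, so the genotypes were not tested against the spread between animals, and each value describes these 2 libraries. How many animals gave each library is not given in the sources used here. Levels are given as FPKM, fragments normalised for transcript length and library size, and intervals are 95% exact binomial (Clopper-Pearson) intervals of the read ratio, which cover counting error only.

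The knockout liver held less Srsf2 transcript than the wild-type liver, and less of many transcripts that hepatocytes make for the blood and for metabolism. Transcripts of cholesterol synthesis, of stress responses, and of macrophages, matrix-producing cells and bile duct epithelium were higher in it. Afp, the fetal plasma protein alpha-fetoprotein, stood at 239 FPKM in the wild-type and 7035 FPKM in the knockout library, 29.5-fold higher (29.0 to 30.0). Alb, which encodes serum albumin, stood at 50399 and 25492 FPKM, 1.98-fold lower in the knockout (1.97 to 1.98). The knockout library also held transcripts of the exocrine pancreas, of skeletal muscle and of the Y chromosome that were near or at 0 reads in the wild-type library.

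Srsf2 itself had 1998 reads in the wild-type and 832 in the knockout library, or 27.9 and 11.8 FPKM. The knockout level was 0.421 of the wild-type level (0.388 to 0.457), a log2 ratio of -1.18, or -1.73 relative to the median of all genes. Which part of the gene was removed, and in which liver cells, is not given in the sources used here, so the remaining reads cannot be assigned to other cells or to the rest of the gene. On the log2(FPKM + 1) scale used for the 2-fold rule throughout, among the 11 tested SR proteins Srsf2 was the member at least 2-fold lower, and Srsf5 was the member at least 2-fold higher (0 members after centring), at 27.3 and 57.2 FPKM. The median log2 ratio of the SR proteins other than Srsf2 was 0.70, close to the median of 0.55 over all tested genes. Core spliceosome and hnRNP genes had a median of 0.56 (0.01 relative to all genes) over 35 tested members, with 4 at least 2-fold higher and 0 lower (1 and 0 after centring). Among them Ptbp2, a polypyrimidine-tract binding splicing repressor best known from neurons, stood at 1.30 and 10.9 FPKM, 8.40-fold higher (7.01 to 10.2). Neither list stood apart from random lists of the same size and expression, with percentiles of 75.2 for the SR proteins and 45.6 for the spliceosome list.

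Of 12477 genes with an FPKM of at least 1 in either library, 2396 were at least 2-fold higher and 368 at least 2-fold lower in the knockout, so 86.7% of these genes were higher. The ratios were shifted as a whole. The median log2 ratio was 0.55, and 84.5% of the tested genes had a higher value in the knockout library. The 20 most abundant transcripts, Alb among them, took 37.5% of the wild-type reads and 21.5% of the knockout reads, and Alb alone took 12.2% and 6.17%. After centring on the median of all genes, 708 genes were at least 2-fold higher and 831 at least 2-fold lower, with 46.0% of them higher. For this reason list medians are given as deposited and then relative to the median of all genes, and counts of list members are followed by the count after centring. Without the genes on the sex chromosome, pancreatic and skeletal muscle lists the counts were 2358 higher and 367 lower. Genes outside those lists stayed in, among them the exocrine pancreas genes Rnase1 and Ctrl. These counts therefore do not measure how much sex or other tissue adds to the differences.

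**Figure D1:**
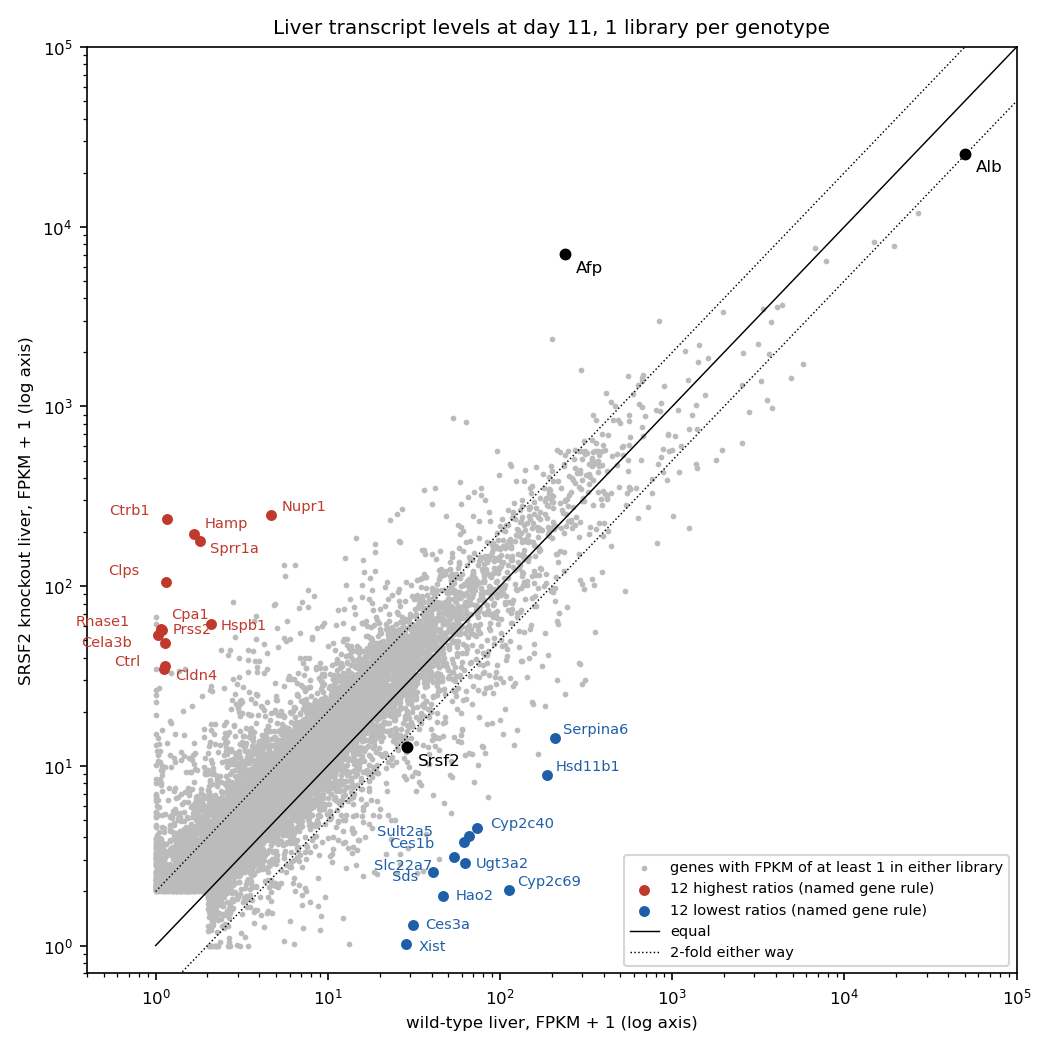
Each point is a gene with an FPKM of at least 1 in either library, with FPKM + 1 in wild-type liver on the x axis and in SRSF2 knockout liver on the y axis, both on log axes, 1 library per genotype. The 12 highest (red) and 12 lowest (blue) ratios of the named gene rule are marked, with Srsf2, Alb and Afp in black, and most of the cloud lies above the line of equality, with a median log2 ratio of 0.55.

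Among well-expressed genes detected in both libraries, the 12 with the highest ratios held digestive enzymes, stress-induced genes and epithelial genes. Hamp, which encodes the iron-regulating hormone hepcidin, stood at 0.668 and 194 FPKM, 291-fold higher (141 to 724). Sprr1a, a cornified envelope precursor of squamous epithelium, stood at 0.811 and 178 FPKM. Nupr1, a stress-induced chromatin protein, stood at 3.67 and 248 FPKM, 67.6-fold higher (52.5 to 88.5). The small heat shock protein gene Hspb1 was at 1.09 and 60.4 FPKM, and Cldn4, which encodes a tight junction protein, was at 0.125 and 33.4 FPKM. The other 7 genes encode secreted products of the exocrine pancreas. They were Ctrb1 (0.170 and 235 FPKM), Clps (0.153 and 105 FPKM), Cpa1 (0.0717 and 56.6 FPKM), Prss2 (0.0913 and 55.8 FPKM), Rnase1 (0.0389 and 52.8 FPKM), Cela3b (0.126 and 47.1 FPKM) and Ctrl (0.127 and 34.8 FPKM). Rnase1 had 1 read in the wild-type library, so its ratio of 1358 carries an interval of 243 to 53681.

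The 12 genes with the lowest ratios were mostly enzymes and transporters of hepatocytes. Cyp2c69 stood at 111 FPKM in the wild-type and 1.03 FPKM in the knockout library, 108-fold lower (82.4 to 149.5), and Cyp2c40, another member of this cytochrome P450 family, stood at 72.6 and 3.48 FPKM. Hsd11b1, which regenerates active glucocorticoid, stood at 188 and 7.91 FPKM, 23.7-fold lower (21.1 to 26.8). Serpina6, which encodes the corticosteroid-binding globulin of plasma, stood at 208 and 13.3 FPKM, 15.7-fold lower (14.3 to 17.2). The peroxisomal oxidase gene Hao2 was at 45.6 and 0.897 FPKM, the carboxylesterase genes Ces3a and Ces1b at 30.1 and 0.298 FPKM and at 60.5 and 2.77 FPKM. Ugt3a2, a glycosyltransferase gene, was at 61.9 and 1.87 FPKM, Slc22a7, an organic anion transporter gene, at 52.8 and 2.09 FPKM, Sult2a5, a sulfotransferase gene, at 64.8 and 3.06 FPKM, and Sds, which encodes serine dehydratase, at 39.9 and 1.56 FPKM. Xist, the RNA of the inactive X chromosome, completed the set at 27.4 and 0.0138 FPKM. The Cyp2c, Ces1, Sult2a and trypsinogen families hold near-identical members, and how reads shared among them were counted is not stated, so the split between members is uncertain.

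The gene lists were compared with 10000 random lists of the same size and expression, as a description of these libraries. Of 41 lists, 12 had a median in the highest 2.5% of the random lists and 14 in the lowest 2.5%. The other 15 lay between. With no list effect and genes that vary independently, about 2.05 lists would lie outside. Genes of a list can vary together and some lists share genes, so more could lie outside without an effect of genotype.

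**Figure D2:**
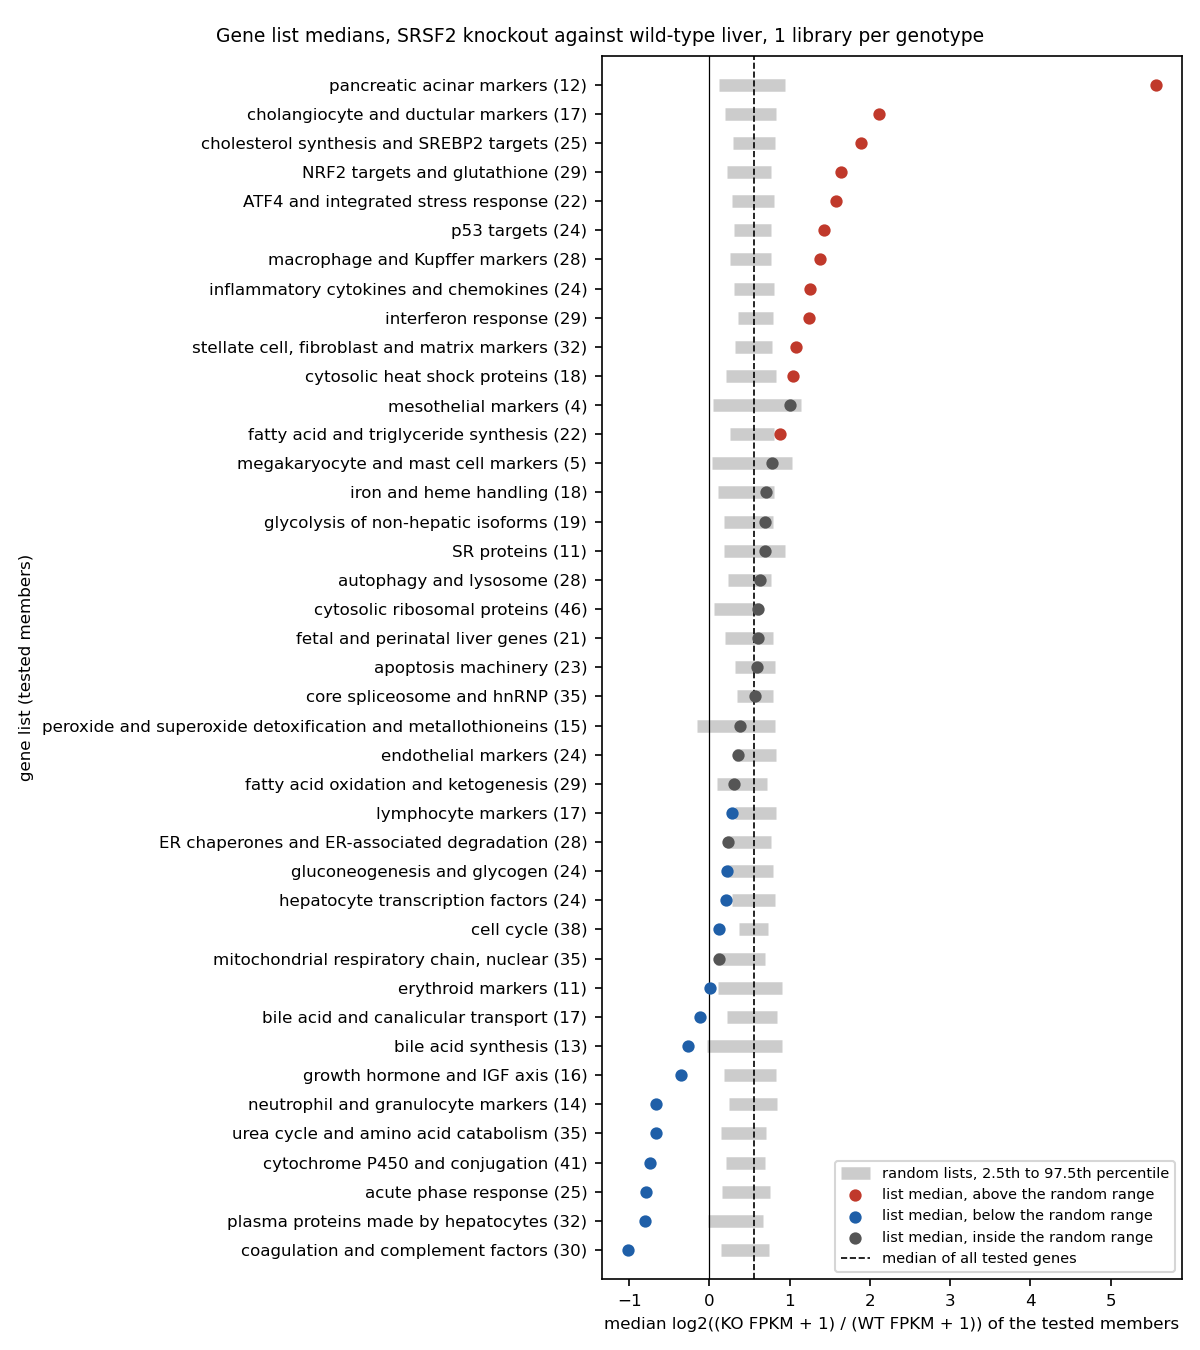
Each dot is the median log2 ratio of FPKM + 1, knockout over wild type, of the tested members of a gene list (number of members in brackets), and grey bars span the central 95% of random lists of the same size and expression. The dashed line marks the median of all tested genes, 0.55, and medians run from -1.01 for coagulation and complement factors to 5.56 for pancreatic acinar markers.

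Plasma proteins made by hepatocytes had a median log2 ratio of -0.81, or -1.36 relative to all genes, with 13 of 32 tested members at least 2-fold lower and 2 higher (21 and 1 after centring). The iron carrier gene Trf stood at 19368 and 7809 FPKM, 2.48-fold lower (2.47 to 2.49), and Itih1, an inter-alpha-trypsin inhibitor heavy chain, stood at 299.7 and 27.5 FPKM, 10.9-fold lower (10.4 to 11.4). Apoa4, an apolipoprotein, went the other way at 52.7 and 861 FPKM, 16.3-fold higher (15.7 to 17.1). Coagulation and complement factors had a median of -1.01 (-1.56 relative to all genes), with 15 of 30 members at least 2-fold lower and 0 higher (25 and 0 after centring). An example was complement C5, encoded by Hc, at 180.3 and 20.6 FPKM. The acute phase list had a median of -0.79 (-1.34), with 10 of 25 members lower and 7 higher (13 and 5 after centring). Saa1, a serum amyloid A gene with a near-identical copy, stood at 83.8 and 5.75 FPKM, and Cd14, a co-receptor for lipopolysaccharide, at 2.90 and 32.2 FPKM. The percentile was 0 for each of these 3 lists.

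Further lists of hepatocyte metabolism lay in the lowest 2.5% of random lists, with members on both sides. The urea cycle and amino acid catabolism list had a median of -0.67 (-1.22 relative to all genes, percentile 0), with 14 of 35 members at least 2-fold lower and 3 higher (22 and 1 after centring). Otc, the ornithine transcarbamylase gene of the urea cycle, stood at 73.1 and 9.13 FPKM, and Hal, which encodes histidine ammonia-lyase, at 36.4 and 3.20 FPKM, while the urea cycle gene Ass1 stood at 668 and 1447 FPKM. Cytochrome P450 and conjugation genes had a median of -0.75 (-1.30, percentile 0), with 17 of 41 members lower and 8 higher (23 and 4 after centring). Cyp2e1, which oxidises ethanol and other small molecules, stood at 1938 and 568 FPKM, 3.41-fold lower (3.36 to 3.46). Bile acid synthesis genes had a median of -0.26 (-0.82, percentile 0.755), with 4 of 13 members lower and 2 higher (5 and 1 after centring). Of these, Akr1c6 stood at 213 and 29.2 FPKM and Cyp27a1, the sterol 27-hydroxylase, at 20.5 and 98.2 FPKM. Bile acid and canalicular transport genes had a median of -0.11 (-0.67, percentile 0.03), with 4 of 17 members lower and 4 higher (7 and 3 after centring). The bile acid uptake carrier gene Slc10a1 stood at 206 and 96.4 FPKM, and Abcb4, the canalicular phospholipid exporter, at 31.8 and 107 FPKM. As stated for the single genes, the libraries also differed in Xist and in Y-linked transcripts. Of the 12 genes with the lowest ratios, 3 belong to a list of adult female-biased liver genes drawn up after the results were seen. Xist and Sult2a5, also among the 12, are not on that list.

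Gluconeogenesis and glycogen genes and hepatocyte transcription factors lay low among random lists by a smaller margin, and their medians changed sign with the scaling. The gluconeogenesis list had a median of 0.22 as deposited and -0.33 relative to all genes (percentile 2.36), with 3 of 24 members at least 2-fold lower and 4 higher (5 and 1 after centring). It no longer stood apart with a pseudocount of 0.1 (percentile 3.08), on the TPM scale (2.64) or without the 20 most abundant genes (3.84). Khk, the fructokinase gene, stood at 74.8 and 17.7 FPKM. The transcription factor list had a median of 0.21 as deposited and -0.35 relative to all genes (percentile 0.74), with 1 of 24 members lower and 1 higher (5 and 0 after centring). These were the nuclear receptor genes Nr1i3, at 23.9 and 9.53 FPKM, and Nr1i2, at 15.1 and 34.2 FPKM. Growth hormone and IGF axis genes had a median of -0.36 (-0.91, percentile 0), with 4 of 16 members lower and 1 higher (7 and 1 after centring). Igfals, which encodes the acid-labile subunit that holds insulin-like growth factors in plasma, stood at 43.0 and 2.04 FPKM, 21.1-fold lower (17.6 to 25.5). The growth factor gene Igf2 stood at 811 and 173 FPKM, and the binding protein gene Igfbp1 at 839 and 2977 FPKM.

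Genes of cholesterol synthesis and other SREBP2 targets had a median log2 ratio of 1.89, or 1.33 relative to all genes (percentile 100). At least 2-fold higher values were found for 19 of 25 members, and after centring 17 were higher and 1 lower. Fdps, the farnesyl diphosphate synthase gene, stood at 3.91 and 78.2 FPKM, 20.01-fold higher (17.0 to 23.8). Idi1, the isopentenyl diphosphate isomerase gene, was 24.98-fold higher (20.9 to 30.2) and Sqle, the squalene epoxidase gene, 22.4-fold higher (17.97 to 28.3). The fatty acid and triglyceride synthesis list had a median of 0.88 (0.33, percentile 99.4), with 9 of 22 members higher and 1 lower, but 3 higher and 3 lower after centring. It no longer stood apart with a pseudocount of 5 (percentile 97.2), a filter of 5 FPKM (97.0) or on the TPM scale (96.8). Scd1, which encodes the stearoyl-CoA desaturase, stood at 3.45 and 21.5 FPKM. Fatty acid oxidation and ketogenesis genes did not stand apart as a list (median 0.31, or -0.25 relative to all genes, percentile 18.9), although 6 of 29 members were at least 2-fold higher and 0 lower (5 and 3 after centring). The peroxisomal enzyme gene Ehhadh stood at 40.6 and 349 FPKM and Angptl4, an inhibitor of lipoprotein lipase, at 17.7 and 153.9 FPKM.

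Stress response lists were higher in the knockout library. The list of ATF4 and integrated stress response genes had a median of 1.58 (1.02 relative to all genes), with 16 of 22 members at least 2-fold higher and 0 lower (11 and 0 after centring). Ddit3, which encodes the transcription factor CHOP, stood at 2.05 and 38.7 FPKM, 18.9-fold higher (15.1 to 23.96), and Atf3 at 0.439 and 19.1 FPKM. The p53 target list had a median of 1.42 (0.87), with 16 of 24 members higher and 0 lower (10 and 2 after centring, median 0.71 with a pseudocount of 5). Cdkn1a, the inhibitor of cyclin-dependent kinases p21, stood at 7.34 and 86.8 FPKM, 11.8-fold higher (10.6 to 13.2), and Trp53inp1 at 6.11 and 80.8 FPKM. For NRF2 targets and glutathione genes the median was 1.63 (1.08), with 20 of 29 members higher and 0 lower (15 and 0 after centring). Gstp1, a glutathione S-transferase gene, stood at 199 and 2382 FPKM, 11.96-fold higher (11.6 to 12.4), and Ugdh, which makes UDP-glucuronate, at 2.82 and 67.5 FPKM. Each of these 3 lists lay at percentile 100. Cytosolic heat shock proteins had a median of 1.04 (0.49, percentile 99.9), with 9 of 18 members higher and 0 lower (4 and 0 after centring). Hspa1a and Hspa1b, near-identical genes whose reads cannot be divided with certainty, stood at 0.624 and 20.6 FPKM and at 1.41 and 43.2 FPKM.

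By contrast, ER chaperones and ER-associated degradation genes did not stand apart (median 0.23, or -0.33 relative to all genes, percentile 2.99), with 5 of 28 members at least 2-fold higher and 0 lower (1 and 0 after centring). The abundant disulfide isomerase gene P4hb stood at 513 and 536 FPKM. The apoptosis machinery list had a median of 0.60 (0.04, percentile 58.6), with 3 of 23 members higher and 1 lower (0 and 3 after centring), and Bcl2l1, which encodes the survival protein BCL-XL, stood at 7.41 and 19.98 FPKM. Genes of peroxide and superoxide detoxification and metallothioneins had a median of 0.39 (-0.17, percentile 45.0), with 6 of 15 members higher and 1 lower (2 and 2 after centring). Within that list Gpx3, a secreted glutathione peroxidase gene, stood at 3.85 and 78.0 FPKM. Cell cycle genes had a median of 0.13 as deposited and -0.43 relative to all genes, at percentile 0, and 0 of 38 members reached 2-fold in either direction (0 higher and 2 lower after centring). Pcna, the sliding clamp of DNA replication, stood at 21.5 and 29.3 FPKM.

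**Figure D3:**
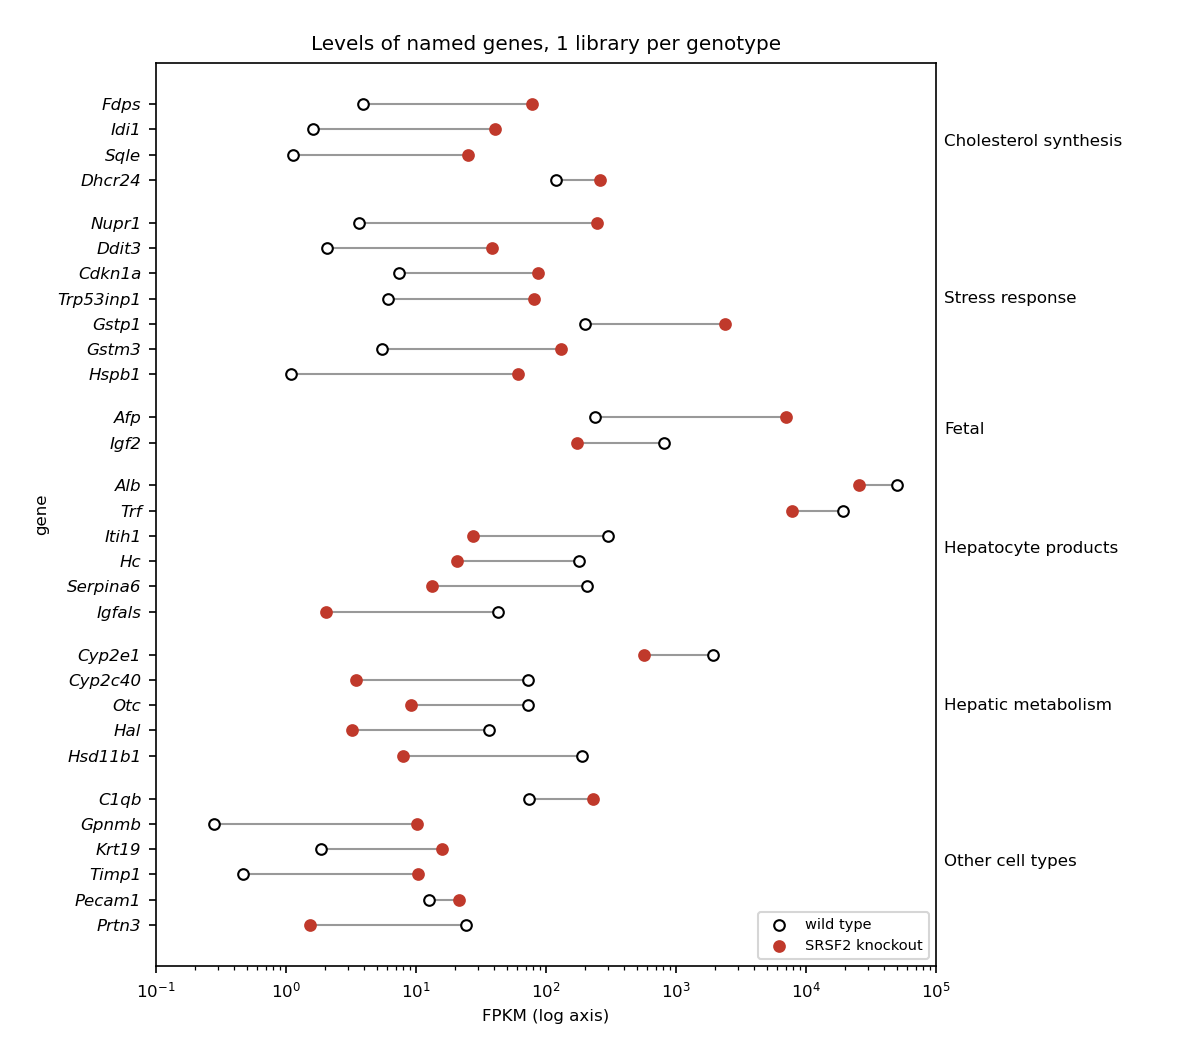
Paired dots give the FPKM of named genes, on a log axis, in wild-type liver (open) and SRSF2 knockout liver (red), 1 library per genotype, with lines joining the 2 values of a gene. Genes of cholesterol synthesis and stress responses lie to the right in the knockout, such as Nupr1 at 3.67 and 248 FPKM, and most hepatocyte products lie to the left, such as Serpina6 at 208 and 13.3 FPKM.

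Members of the fetal and perinatal liver list lay on both sides. The list had a median of 0.61 (0.06 relative to all genes, percentile 75.4), with 8 of 21 members at least 2-fold higher and 5 lower (5 and 6 after centring). Afp lay at the high end, with Tff3, a trefoil peptide of mucous epithelia, at 1.81 and 80.2 FPKM. The plasma glycoprotein gene Ahsg, which is also on the plasma protein list, lay lower at 26610.5 and 11956 FPKM. Igf2, described above and also a member, lay lower as well. Iron and heme handling genes had a median of 0.70 (0.15, percentile 90.3), with 8 of 18 members higher and 4 lower (4 and 5 after centring). Besides Hamp, the gene of the hepcidin inducer Bmp6 stood at 0.328 and 4.48 FPKM. The glycolysis list had a median of 0.69 (0.14, percentile 89.8), with 7 of 19 members higher and 0 lower (4 and 0 after centring). It was drawn up for non-hepatic isoforms but also holds genes abundant in liver, such as Ldha at 667 and 996 FPKM. The aldolase gene Aldoa stood at 64.0 and 313 FPKM. Autophagy and lysosome genes had a median of 0.63 (0.08, percentile 80.1), with 9 of 28 members higher and 0 lower (2 and 0 after centring), and Sqstm1, the autophagy receptor p62, stood at 113 and 478 FPKM. Nuclear genes of the mitochondrial respiratory chain had a median of 0.12 (-0.44, percentile 3.30), and 0 of 35 members reached 2-fold (0 higher and 3 lower after centring). Cytosolic ribosomal proteins had a median of 0.61 (0.06, percentile 96.8), with 2 of 46 members higher and 0 lower (0 and 0 after centring).

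Markers of several other liver cell types were higher in the knockout library. Cholangiocyte and ductular markers had a median of 2.11 (1.55 relative to all genes), with 11 of 17 members at least 2-fold higher and 0 lower (9 and 1 after centring). That median was less than 1 with no filter, at 0.88 over all 22 members, and with a pseudocount of 5, at 0.92. The keratin genes Krt19 and Krt8 stood at 1.86 and 15.8 FPKM and at 76.9 and 351 FPKM. Some of these markers, Krt19 among them, are also made by pancreatic ducts, and Krt8 is also made by hepatocytes. Macrophage and Kupffer markers had a median of 1.38 (0.82), with 18 of 28 members higher and 0 lower (10 and 0 after centring). The complement component gene C1qb stood at 74.5 and 229 FPKM, and Gpnmb and Trem2, which mark lipid-laden macrophages, at 0.278 and 10.1 FPKM and at 0.230 and 8.82 FPKM. Stellate cell, fibroblast and matrix markers had a median of 1.07 (0.52), with 17 of 32 members higher and 0 lower (4 and 1 after centring). Timp1, an inhibitor of metalloproteinases, stood at 0.466 and 10.4 FPKM, while Fn1, the fibronectin gene that hepatocytes also express, stood at 759 and 391.7 FPKM. Inflammatory cytokines and chemokines had a median of 1.25 (0.70), with 14 of 24 members higher and 0 lower (6 and 0 after centring, median 0.58 with a pseudocount of 5), and the chemokine gene Cxcl10 stood at 1.88 and 51.3 FPKM, 27.3-fold higher (20.8 to 36.4). The interferon response list had a median of 1.25 (0.69), with 16 of 29 members higher and 0 lower (12 and 0 after centring, median 0.65 with a pseudocount of 5), and Irf7, a transcription factor of this response, stood at 6.35 and 38.6 FPKM. The percentile was 100 for each of these 5 lists.

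Endothelial markers had a median of 0.36 (-0.20, percentile 4.71), and 0 of 24 members reached 2-fold in either direction (0 higher and 0 lower after centring). Pecam1, a junction protein of endothelium, stood at 12.6 and 21.5 FPKM. Neutrophil and granulocyte markers had a median of -0.66 (-1.21, percentile 0), with 4 of 14 members lower and 0 higher (8 and 0 after centring), and Prtn3, a protease of granulocyte precursors, stood at 24.2 and 1.53 FPKM, 15.8-fold lower (11.4 to 22.4). Erythroid markers had a median of 0.01 as deposited and -0.54 relative to all genes (percentile 0.945), and 0 of 11 members reached 2-fold (0 higher and 3 lower after centring). The alpha-globin genes Hba-a1 and Hba-a2, near-identical copies, stood at 399 and 224 FPKM and at 361 and 206 FPKM. Lymphocyte markers had a median of 0.28 as deposited and -0.27 relative to all genes (percentile 1.27), with 3 of 17 members higher and 0 lower (1 and 2 after centring). The percentile was 5.11 with a pseudocount of 0.1. The megakaryocyte and mast cell list had 5 tested members and a median of 0.79 (0.23, percentile 86.0), with 2 higher and 0 lower (1 and 1 after centring). The mesothelial list had 4 tested members and a median of 1.002 (0.45, percentile 94.4), with 2 higher and 0 lower (0 and 0 after centring).

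Transcripts of the exocrine pancreas were higher in the knockout library than those of any other list fixed beforehand. Pancreatic acinar markers had a median log2 ratio of 5.56 (5.01 relative to all genes, percentile 100), and 12 of 12 tested members were at least 2-fold higher, also after centring. Most of them passed the filter through the knockout library alone, but by reads, without the filter, 13 of 13 listed genes were at least 2-fold higher against a floor of 3 reads. With the 4 members at 0 wild-type reads set to a floor of 3 reads, the median log2 read ratio was 8.90. The list took 370 reads (0.00165%) in the wild-type and 23268 reads (0.105%) in the knockout library. Cel, the bile salt-dependent lipase gene, and Cpb1, a carboxypeptidase gene, had 0 reads in the wild-type library and stood at 66.2 and 60.8 FPKM in the knockout. Against a floor of 3 reads they were 1194-fold and 803-fold higher, with lower limits of the exact interval at 970 and 652. Acta1, the actin gene of skeletal muscle, also had 0 wild-type reads and stood at 33.7 FPKM, 468-fold higher against that floor (lower limit 380). In all, 9 genes reached 10 FPKM in the knockout at 0 FPKM in the wild type, and 0 genes did so the other way.

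Sex-linked transcripts separated the libraries. Xist had 13004 reads in the wild-type and 6 in the knockout library. The Y-linked genes Ddx3y, Eif2s3y and Uty had 0 reads in the wild-type library and 859, 277 and 288 in the knockout library, and Kdm5d had 1 and 442 reads. The wild-type library thus held the transcripts of female liver and the knockout library those of male liver. Sex, genotype and the presence of pancreatic and muscle transcripts differed together between the libraries, so no difference above can be assigned to genotype alone.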

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

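The alternatives set before the data were examined moved the counts of genes in several settings, and 3 alternatives were added later. The genes at least 2-fold higher numbered 3797 with a pseudocount of 0.1, 786 with a pseudocount of 5, 3628 on the TPM scale, 708 after centring, 1208 after rescaling without the 20 most abundant genes, 5914 at 1.5-fold and 344 at 4-fold, against 2396. Those at least 2-fold lower numbered 232 with a pseudocount of 5, 831 after centring, 687 at 1.5-fold and 94 at 4-fold, against 368. On the TPM scale both libraries rise by nearly the same factor, since their deposited FPKM sums were 430662 and 427861. The pseudocount and the filter stayed at 1, so they weigh less on that scale. Of the added alternatives, requiring the whole read ratio interval to lie beyond 2-fold gave 2610 higher and 351 lower. That rule also used no pseudocount, so the interval was not its only change. Leaving out the listed sex chromosome and pancreatic genes gave 2370 and 367, and leaving out the listed muscle genes as well gave 2358 and 367. The log2 ratio of Srsf2 stayed below 0 in each setting, at -0.97 with a pseudocount of 5, -1.73 after centring and -1.49 without the 20 most abundant genes. The median of all genes was 0.68 with a pseudocount of 0.1, 0.30 with 5, 0.31 with no filter, 0.28 without the 20 most abundant genes and 0 after centring, which sets it. Centring turned the medians of hepatocyte transcription factors (-0.35), gluconeogenesis (-0.33), cell cycle (-0.43), erythroid (-0.54) and lymphocyte (-0.27) genes below 0. Rescaling without the 20 most abundant genes did the same (-0.10, -0.068, -0.15, -0.19 and -0.022), and so did a filter of 5 FPKM for erythroid genes (-0.29), with fewer members tested. These 5 lists lay low among random lists in the report, and their sign follows the scaling by construction. The gluconeogenesis list left the outer range with a pseudocount of 0.1, on the TPM scale and without the 20 most abundant genes, the lymphocyte list with a pseudocount of 0.1, and the fatty acid synthesis list with a pseudocount of 5, a filter of 5 FPKM and on the TPM scale. Glycolysis (pseudocount of 5), ribosomal (without the 20 most abundant genes) and mesothelial genes (no filter, TPM scale) entered it. The shifts on the TPM scale follow mainly from the smaller weight of the pseudocount and the filter, and the cause of the others was not tested. A pseudocount of 5 lowered most the medians of acinar (3.59), ductular (0.92), p53 (0.71), inflammatory (0.58) and interferon (0.65) genes, and no filter lowered the ductular and inflammatory medians (0.88 each), all still in the outer range. A filter of 5 FPKM left 3 lists (lymphocyte, megakaryocyte and mesothelial) with too few members for a value. None of the named genes past 2-fold with reads in both libraries changed sign in these settings. The settings could hardly do so, since centring moved each log2 ratio by 0.55, which is less than 2-fold. With 1 library per genotype, depth limits the counting error and says nothing of the spread between animals.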

Other observations

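Of the tests below, the one on islet hormone genes was chosen before its result was seen, and the others, with the added gene lists, were chosen after the results were seen. Genes named here outside the named gene rule were likewise chosen after their values were seen.

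Several gene groups not among the lists fixed beforehand were compared. Of 21 tested immediate early and AP-1 genes, 19 were at least 2-fold higher in the knockout and 0 lower (8 and 0 after centring), with a median log2 ratio of 1.33 (0.77 relative to all genes, percentile 100). Myc, a growth-promoting transcription factor, stood at 1.90 and 24.2 FPKM, and Jun, a subunit of AP-1, at 2.47 and 24.9 FPKM. Genes known from injured epithelium had a median of 2.55 (2.001, percentile 100), with 21 of 22 members higher and 0 lower (16 and 0 after centring). Plat, the tissue plasminogen activator gene, stood at 0.236 and 32.0 FPKM, and Tnfrsf12a, the receptor for the cytokine TWEAK, at 4.61 and 112 FPKM. Lipid droplet proteins and PPAR targets had a median of 0.97 (0.42, percentile 99.8), with 9 of 20 members higher and 2 lower (7 and 2 after centring). Cidec, a lipid droplet fusion protein, stood at 0.484 and 33.4 FPKM, and Plin2, a droplet coat protein, at 76.0 and 319.9 FPKM. Targets of YAP and TEAD did not stand apart from random lists and had a median of 0.81 (0.26, percentile 94.2), with 6 of 14 members higher and 0 lower (5 and 0 after centring), among them Ccn1, a matricellular protein gene, at 2.79 and 37.3 FPKM. Each of these 4 lists shares 1 gene with a list fixed beforehand. The lists were drawn up after the results were seen, and Sprr1a of the injured epithelium list is among the 12 highest ratios. Their counts and percentiles therefore describe the chosen genes and are no independent test.

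Transcripts of other organs were also compared. Skeletal muscle genes had 141 reads in the wild-type and 4949 in the knockout library over 19 genes, and 10 of the genes had 0 wild-type reads. By reads, against a floor of 3 in the wild-type library, 18 of the 19 were at least 2-fold higher. The 13 tested members had a median of 2.498 (1.94 relative to all genes, percentile 100), or 6.95 as a log2 read ratio with the 6 members at 0 wild-type reads set to 3 reads. Besides Acta1, the fast muscle genes Mylpf and Ckm had 2 and 317 reads and 1 and 357 reads. Heart muscle genes had 29 and 257 reads over 10 genes, and 5 of the 10 were at least 2-fold higher by reads. Most of the reads were of Actc1 (0 and 99) and Tnnt2 (22 and 85), while Myh6 had 0 in both libraries, Tnni3 4 and 3, and Myl2 and Nppa 0 and 1 each. The median was 1.23 over 3 tested members (0.68, percentile 98.2), or 5.06 as a log2 read ratio with that floor. A second list of 12 acinar genes had 1462 and 5987 reads, of which 1430 and 4607 were of Pnliprp1 alone, a gene at 33.3 FPKM in wild-type liver. The median was 2.11 over 8 tested members (1.56, percentile 100), or 5.77 with that floor. In the wild-type library 0 of the 19 skeletal muscle genes, 0 of the 10 heart muscle genes and 2 of these 12 acinar genes reached 1 FPKM. Most tested members thus passed the filter through the knockout library alone, so their medians and percentiles lean upward by construction. The adipocyte list had a median of 0.76 over 4 tested members (0.21, percentile 76.3), and Adipoq, the adiponectin gene, had 0 and 4 reads. Intestinal epithelium genes had a median of 1.31 over 6 tested members (0.76, percentile 99.7), with 3 higher and 0 lower (3 and 0 after centring), and 6 of the 12 listed genes were at least 2-fold higher by reads. Cdh17 had 2 and 243 reads, Muc2 4 and 102, Lgals4 113 and 442, and the intestinal regulator gene Cdx2 0 in both libraries. No explanation was tested for these values.

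The acinar transcripts of the knockout library may come from pancreatic tissue in the KO sample, that is, collected with the knockout liver. Pancreas would bring islet transcripts too, and 5 of 7 islet hormone genes had at least 10 reads in the knockout library and at least 4 times the wild-type reads, with Ins1 highest at 41 reads and 123 reads in all against 0. The most abundant acinar transcript, Ctrb1, reached 235 FPKM. Expression within the liver as an effect of the genotype stays open, since only 1 knockout library was at hand to check it.

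The lower level of adult female-biased genes in the knockout library could follow from the sex of the libraries or from the lower level of hepatocyte transcripts in general. Of 30 tested female-biased genes (the list shares 8 genes with lists fixed beforehand), 15 were at least 2-fold lower and 2 higher (18 and 1 after centring, median -0.93, or -1.49 relative to all genes). A general fall of hepatocyte transcripts was tested by drawing random lists from 214 genes of the hepatocyte lists (median -0.46), and the female-biased median lay at percentile 2.85, just inside the range that such a fall allows. The sex explanation predicts higher male-biased genes only if the adult bias is already present at day 11, which was not tested. The male-biased list shares 8 genes with lists fixed beforehand, such as Gstp1 and Hc, and shares Spink1 with the second acinar list. The tested male-biased genes went both ways, with 8 of 19 higher and 5 lower (5 and 9 after centring). Their median was 0.12, or -0.44 relative to all genes (percentile 0.51), and decides nothing. Some listed male-biased genes were near 0 reads in both libraries, such as Elovl3 at 2 and 1 and Cyp4a12a at 0 and 9. Sex and genotype differ together here and cannot be told apart for these genes.

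Macrophage, stromal and ductular markers might be higher because hepatocytes made up a smaller share of the knockout sample. A smaller share would raise the markers of the other cell types alike. The macrophage median exceeded the endothelial median by 1.03 on the log2 scale (bootstrap 95% interval 0.59 to 1.34, 28 and 23 genes). A smaller share alone would not account for that difference between the macrophage and endothelial lists in these libraries. Both medians were already known when the comparison was chosen, so it is no independent test. The interval covers the spread among the listed genes, not between animals. Stromal and ductular medians were not compared with the endothelial median. A change in these cell types as an effect of the genotype stays open and was checkable in only 1 knockout library. The difference in sex and the pancreatic tissue weighed above, which would bring duct and stromal cells of its own, were not tested for this pattern.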
